A study of Mus musculus with 17 samples.

How the data were processed

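Poly(A) RNA from the medial prefrontal cortex (mPFC) of 17 wild-type mice was sequenced. Per the labels, mice of both sexes received an adeno-associated virus of serotype 2/5 carrying either iβARK fused to mCherry or mCherry alone when they were 3 to 4 months old, and tissue was profiled 45 days later. iβARK is a peptide inhibitor derived from the β-adrenergic receptor kinase 1 (GRK2) that binds and blocks Gq signalling. It is used to lower calcium signalling in astrocytes. The labels do not name the promoter or the cells that carried the vector. Per the labels' protocols, RNA was extracted with a column kit, samples with a RIN above 7 were enriched on poly(T) beads, and libraries were made with a directional kit and sequenced on an Illumina NovaSeq 6000.

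The deposited table holds estimated counts per gene, written as whole numbers and not normalized, with 1 column for each of the 17 libraries. Per the submitters' processing notes, fastp 0.23.2, Bowtie2 2.4.5, HISAT2 2.2.1 and RSEM 1.3.3 were used with the GRCm38 build, with no role or order given. The counting step, its strand setting and the gene annotation are not given in the sources used here. RSEM shares reads that match several places among the genes, so values of near-identical genes are uncertain. Gm28661, a nuclear copy of mitochondrial sequence, held 0.231 to 0.473% of the counts. The mitochondrial gene mt-Nd4 had a count of 0 in 10 libraries and up to 619 CPM in the other 7, so its values are uncertain. Overlapping and antisense genes are uncertain too, because the strand setting is not known. The table had 35048 rows, of which 30806 carried Ensembl identifiers, 2885 were assembled loci named MSTRG and 1357 were named by other identifiers. Symbols are those of the table itself. Coordinates are 1-based and come from the GENCODE M21 annotation of GRCm38, in which 29310 of the Ensembl identifiers were found and 1496 were not. No row named the vector or mCherry, so the delivered transgene was not measured here.

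Totals were 24696720 to 34130357 counts per library and 21803 to 24739 rows had a count. Mitochondrially encoded genes took 3.55 to 6.40% of the counts. Between replicates of one group the chi-square per gene was 23.6 to 78.4 and the correlation of log2 CPM 0.945 to 0.974 over 29 pairs of libraries, so no library was a copy of another. The labels do not say that each library came from its own mouse. The p-values of single genes measure the spread between these libraries. The gene list test described below (camera) compares members with other genes. With its preset correlation its p-values rest largely on the spread between genes, not between libraries.

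The libraries formed 4 groups, male mCherry (n = 3), male iβARK (n = 4), female mCherry (n = 5) and female iβARK (n = 5). The counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.951 to 1.10), the default expression filter by group (a minimum count of 10 and a minimum total of 15) and a quasi-likelihood F test. One fit of all 17 libraries with the 4 group means gave every contrast: the mean of the male and the female effect of iβARK, the effect in each sex, the male effect minus the female effect, and male minus female mCherry mice. The filter left 19839 features, 18561 of them with Ensembl identifiers. P-values were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. Fold changes are log2 with the standard error (SE) from the fit, and CPM values use the TMM factors.

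In all, 42 gene lists (cell type markers, pathways and 1 list of sex-linked genes) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. Of 970 list entries 969 matched a symbol and 947 were tested. Lists share members: 13 of the 25 astrocyte markers and 7 of the 12 genes of the A1 list are also in another list. Camera was repeated with an estimated correlation, and fry was run. Exact two-sided permutation tests of each list's score, the mean log2 CPM of its members in a library, permuted treatment within sex. They covered 41 lists, and were chosen after seeing the data. Genes were named by a fixed rule: those passing the threshold with at least 1 CPM in a group, up to 12 each way over both sexes (and of one sign in both sexes), 8 each way in a sex, 5 each way for the interaction and 4 each way for the sexes. Predicted genes were named only where fewer than 3 others qualified. Where none passed, up to 5 each way with the smallest p were named. Every tested member of the vector target list, the label check genes and 2 to 4 members of each described list with the smallest p were named too. The lists, the naming rule, the tests and most alternatives were fixed before the data were examined.

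On simulated counts for these 19839 features the contrast of both sexes recovered 55.2% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 97.0% of 66 changed 4-fold, with 6 false among 163 calls. In males these shares were 14.9%, 53.7% and 77.3%, with 2 false among 99 calls. In females they were 16.4%, 70.1% and 86.4%, with 5 false among 120 calls. The changed genes were drawn from those with a mean of at least 1 CPM. Many changed at once, which eases the Benjamini-Hochberg threshold, and counts varied independently between libraries. These shares therefore need not hold for genes under 1 CPM, for few changed genes or for libraries that vary together. Camera, tested on simulated independent genes, called the list of astrocyte markers after it was lowered by 0.5 in males (a log2 shift of -0.5), and 1 of the other lists.

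The labels give each library a batch number that equals its replicate number and runs from 1 in each group, so libraries of one number were taken to share a batch. The correlation across genes of deviations from the group mean was -0.01 to 0.03 for the 5 same-number pairs of females and -0.06 to 0.10 for the 3 of males. Different-number pairs averaged -0.01 in both sexes, but ran from -0.14 to 0.14 in females and from -0.16 to 0.16 in males. The fit that gives the reported values had no block. Other settings tried were other size factors, DESeq2 1.42.0, limma-voom, other filters, the number as a block (over all libraries or within sex), a threshold of 0.1, simpler designs, single pairs of groups, and leaving out each library in turn. The counts of calls were also compared with those from other splits of the same libraries. Covariates for the myelin and the ribosomal protein score, other size factors and the block within sex for the lists, and the lists without mt-Nd4 were added after seeing the data.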

Results

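The mPFC transcriptome was measured in 17 libraries from wild-type mice, 7 from males and 10 from females, that carried iβARK-mCherry or mCherry alone. The design asks how blocking Gq signalling with iβARK changes gene expression in this cortex and whether the sexes respond alike. Male mCherry (n = 3) and male iβARK (n = 4) libraries held 29.5 ± 4.31 M and 29.0 ± 3.78 M counts (mean ± SD). Female mCherry (n = 5) and female iβARK (n = 5) libraries held 28.2 ± 1.73 M and 27.8 ± 1.15 M counts. Mitochondrially encoded transcripts took 5.33 ± 0.933% and 4.86 ± 0.513% of the counts in the male groups, and 4.04 ± 0.544% and 4.16 ± 0.373% in the female groups.

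Sex-linked genes followed the sex labels in every library. Ddx3y, a Y-linked RNA helicase gene, averaged 33.9 ± 6.12 CPM in male mCherry mice (SD, n = 3) and 0.0299 ± 0.041 CPM in female mCherry mice (SD, n = 5). Xist, the RNA that silences 1 X chromosome in females, averaged 0.0809 ± 0.14 and 418 ± 147 CPM in the same groups. Uty, Kdm5d and Eif2s3y averaged 11.8 ± 5.98, 15.2 ± 5.21 and 17.5 ± 4.24 CPM in male mCherry mice, and at most 0.0622 ± 0.105 CPM in female mCherry mice. Eif2s3x, the X-linked partner of Eif2s3y, was lower in males (log2 fold change -0.60, SE 0.09, adjusted p = 0.00596; 0.0727 with the replicate number as a block and 0.278 with it within sex). Its call was also lost without male mCherry replicate 1 (0.0829) or male mCherry replicate 3 (0.0563), and with the mCherry libraries fitted alone (0.271). Among mCherry mice 8 features differed between the sexes, 5 higher and 3 lower in males. The others were the predicted gene Gm55585 (0 CPM in male and 43.1 ± 21.5 CPM in female mCherry mice, adjusted p = 7.75e-06, and 0.148 with the block within sex) and the assembled locus MSTRG.35445, named after its values were seen (1.85 ± 0.747 and 0 CPM, adjusted p = 0.00372; 0.195 with the block, 0.298 with it within sex and 0.0771 with the mCherry libraries fitted alone). With limma-voom the calls of Xist (adjusted p = 0.509) and Gm55585 (adjusted p = 0.607) were lost. The sex-linked list passed with the preset correlation (adjusted p = 6.8e-16) and with an estimated correlation (adjusted p = 3.73e-05).

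Over both sexes, genes of the interferon response were higher in iβARK mice than in mCherry mice. All 30 tested members were positive, with a median log2 fold change of 1.56. The members with the smallest p were Ifit1, which binds viral RNA (2.97, SE 0.58), and Ifi27l2a (3.38, SE 0.74). Rtp4 (2.03, SE 0.46) and Xaf1 (1.58, SE 0.36) followed, and each of the 4 had an adjusted p of 0.252 over all genes. Of the 30 members 28 passed when adjusted over the list alone and 0 over all genes in edgeR. At an unadjusted p under 0.05 there were 28, DESeq2 called 8 over all genes, and limma-voom called 0. The list rose (camera adjusted p = 2.35e-23; adjusted p = 0.245 with an estimated correlation) and passed in all 17 fits that left out a library. Its score differed by 1.32 (exact two-sided permutation p = 0.0248, adjusted p = 0.255 over 41 lists). The list of antigen presentation genes rose too, with 18 of 18 members positive and a median of 0.93 (adjusted p = 9.67e-08; adjusted p = 0.448 with an estimated correlation). It included the class I gene H2-Q7 (2.24, SE 0.57, adjusted p = 0.344) and B2m, the class I light chain (0.81, SE 0.30, adjusted p = 0.536), and 1 member passed when adjusted over the list alone. H2 genes are near-identical paralogs that share reads, so their single values are uncertain. Blood cell and lymphocyte markers were higher as well, with a median of 0.38 and 14 of 16 positive (adjusted p = 0.000892; adjusted p = 0.266 with an estimated correlation). Among genes with a mean of at least 1 CPM this list did not pass (adjusted p = 0.156), and its mean went from 0.76 to 1.55 without male mCherry replicate 3. Of the T cell genes Cd8a was at 2.14 (SE 0.80) with a mean of 0.505 CPM, Cd3g at 2.24 (SE 1.04) with 0.428 CPM and Cd3e at 1.63 (SE 0.78) with 0.521 CPM. Trac was at 0.74 (SE 0.65) with 0.841 CPM, Cd4 at 0.31 (SE 0.51) with 1.3 CPM and Trbc2 at 0.19 (SE 0.13) with 8.03 CPM. The hemoglobin gene Hbb-bs was at -0.08 (SE 0.16) and a mean of 48.2 CPM.

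**Figure D1:**
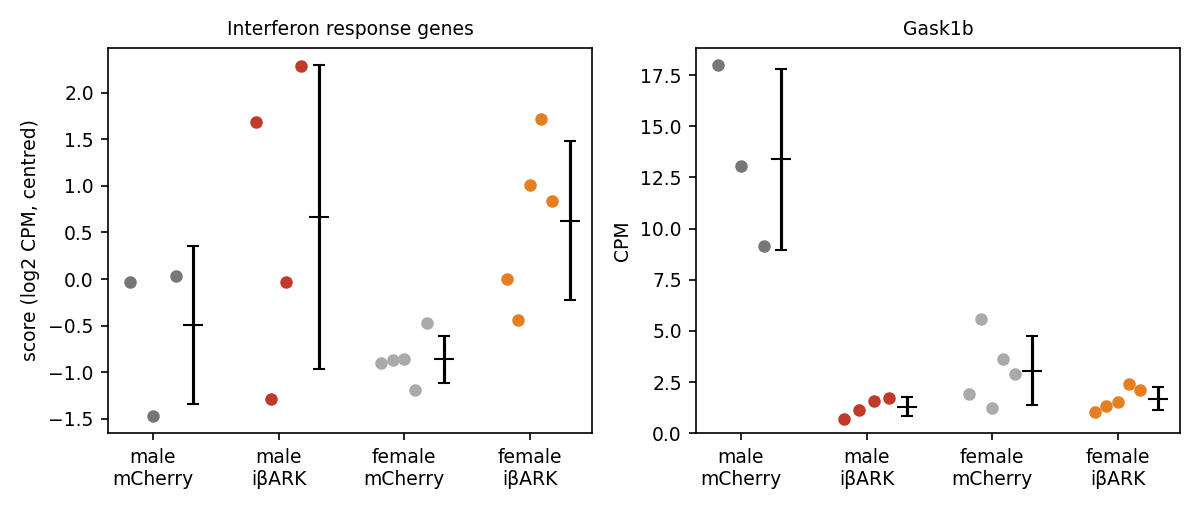
Interferon response score (mean log2 CPM of 30 genes, centred over all libraries, left) and CPM of Gask1b (right) by group, with points for libraries and bars for the mean and SD. All 5 female iβARK libraries lay above the highest female mCherry library in the score, against 2 of the 4 male iβARK libraries above the highest male mCherry library.

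Astrocyte genes were lower in iβARK mice over both sexes, with a median log2 fold change of -0.38 in males and -0.04 in females, where the list did not pass (adjusted p = 0.663). Of 25 astrocyte markers 23 were negative, with a median log2 fold change of -0.23 (adjusted p = 1.29e-08; adjusted p = 0.245 with an estimated correlation). They included Glul, the glutamine synthetase that recycles glutamate (-0.26, SE 0.07), Slc1a3, a glutamate transporter (-0.32, SE 0.09), Plpp3 (-0.32, SE 0.10) and Slc4a4, a bicarbonate transporter (-0.36, SE 0.12). Of the 25 markers 4 passed when adjusted over the list alone and 0 over all genes in edgeR, DESeq2 and limma-voom, with 12 at an unadjusted p under 0.05. The lists of astrocyte homeostasis genes (median -0.18, 18 of 23 negative, adjusted p = 3.93e-06; adjusted p = 0.232 with an estimated correlation) and secreted synaptogenic factors (median -0.13, 19 of 29 negative, adjusted p = 0.00555; adjusted p = 0.247 with an estimated correlation) fell as well. Of their members 3 in each passed when adjusted over the list alone, among them Sparc (-0.31, SE 0.09), Tnc (-0.85, SE 0.26) and Thbs4 (-1.69, SE 0.53). In females the scores of the homeostasis and the secreted factor list differed by -0.002 and -0.022. Endothelial markers rose, with 16 of 18 positive and a median of 0.24 (adjusted p = 1.89e-05; adjusted p = 0.245 with an estimated correlation), from medians of 0.49 in males and -0.09 in females (adjusted p = 0.239). Vwf, a clotting factor carrier of endothelium (0.75, SE 0.22), and Ly6a (0.55, SE 0.17) passed when adjusted over the list alone.

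Several metabolic and hormone-responsive lists fell by small amounts over both sexes. Cholesterol synthesis genes had a median of -0.11 with 20 of 23 negative, among them Idi1 (-0.25, SE 0.08), Msmo1 (-0.26, SE 0.09) and Dhcr7 (-0.25, SE 0.09). This list passed camera (adjusted p = 4.17e-05; adjusted p = 0.0969 with an estimated correlation), fry (adjusted p = 0.0202) and the exact permutation of its score (p = 0.00113, adjusted p = 0.0465 over 41 lists). Glucocorticoid-responsive genes had a median of -0.23 with 18 of 23 negative (adjusted p = 5.69e-05; adjusted p = 0.227 with an estimated correlation), and a score difference of -0.04 in females. When adjusted over the list alone 4 of them fell, among them the kinase gene Sgk1 (-0.64, SE 0.16), and 1 rose, Cdkn1a (0.28, SE 0.09). Ribosomal protein genes had a median of -0.18 with 75 of 78 negative (adjusted p = 6.89e-11; adjusted p = 0.661 with an estimated correlation), and nuclear respiratory chain genes had a median of -0.09 with 66 of 73 negative (adjusted p = 2.35e-05; adjusted p = 0.671 with an estimated correlation). The respiratory chain list did not pass with the ribosomal protein score as a covariate (adjusted p = 0.859). Without male mCherry replicate 1 the mean of the ribosomal list went from -0.18 to -0.10, and that of the astrocyte homeostasis list from -0.13 to -0.09.

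A further 9 lists passed camera over both sexes but lost their call in 2 or more of the 17 fits that left out a library. Higher were excitatory neuron markers (median 0.10, adjusted p = 0.0373, 0.0576 with the replicate number as a block and 0.095 with it within sex), upper layer markers (0.22, adjusted p = 0.0437), the A1 list of reactive astrocyte genes (0.53, adjusted p = 0.0157), cytokine and chemokine genes (0.13, adjusted p = 0.0248, and 0.0682 with the block within sex), immediate early genes (0.13, adjusted p = 0.0437, and 0.0641 with the block), presynaptic vesicle genes (0.09, adjusted p = 0.0315) and DNA damage response genes (0.09, adjusted p = 0.0253). Lower were myelin markers (-0.27, adjusted p = 0.00274) and microglial activation genes (-0.21, adjusted p = 0.0437, and 0.114 with the block). With an estimated correlation their adjusted p was 0.227 for DNA damage response genes and 0.661 or 0.671 for the other 8. The call of the A1 list was lost without male mCherry replicate 2 (adjusted p = 0.213) or male iβARK replicate 1 (0.155), and that of DNA damage genes without male mCherry replicate 2 (0.0543), female mCherry replicate 2 (0.0588) or female iβARK replicate 4 (0.0537). That of myelin markers was lost without male mCherry replicate 2 (0.0954), male mCherry replicate 3 (0.119), male iβARK replicate 2 (0.0666) or female iβARK replicate 1 (0.0674). The other 6 lost it in 7 to 10 of the 17 fits, with the highest adjusted p at 0.151, 0.455 and 0.281 for excitatory neuron, immediate early and presynaptic genes (without male iβARK replicate 3). It was 0.193 for upper layer markers (without male iβARK replicate 2), 0.288 for cytokine genes (without male mCherry replicate 2) and 0.567 for microglial activation genes (without male mCherry replicate 3). With the myelin and the ribosomal score as covariates the adjusted p was 0.0756 and 0.379 for excitatory neuron markers, 0.452 and 0.269 for upper layer markers, and 0.0812 and 0.589 for immediate early genes. It was 0.217 and 0.976 for presynaptic genes and 0.452 and 0.625 for microglial activation genes, whose means turned to -0.01 and 0.01 with the ribosomal score. Cytokine genes did not pass among genes with a mean of at least 1 CPM (0.0631). In fits that kept the call, means went from -0.32 to -0.52 for myelin markers (without female iβARK replicate 3) and from -0.19 to -0.40 for microglial activation genes (without male iβARK replicate 1). Means in the fits without a library that lost the call are not given here. In all 20 of 42 lists passed, 11 higher and 9 lower. With an estimated correlation 0 did, fry called 1, and 6 had an unadjusted exact permutation p under 0.05.

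Among single genes, Gask1b, which encodes a Golgi-associated protein, fell over both sexes. It lies on chromosome 3 from 79884533 to 79946280 (ENSMUSG00000027955, plus strand, GRCm38). It fell by 2.11 on the log2 scale (SE 0.29, adjusted p = 0.0145), from 13.4 ± 4.43 to 1.29 ± 0.464 CPM in males (n = 3 and 4), and it averaged 3.04 ± 1.69 and 1.68 ± 0.573 CPM in female mCherry and iβARK mice (n = 5 and 5; log2 fold change -0.85, SE 0.37, adjusted p = 1.00). Its log2 difference between male and female mCherry mice was 2.14 (adjusted p = 0.0872). It was the 1 gene of 19839 that passed in edgeR, where 1411 had an unadjusted p under 0.05. limma-voom called 1 gene and DESeq2 55, 31 higher and 24 lower. The call was lost with the replicate number as a block within sex (adjusted p = 0.172), and without male mCherry replicate 1 (0.0765), male mCherry replicate 2 (0.0512) or male iβARK replicate 2 (0.0566). It was lost too in the additive fit (0.294), with no sex term (0.280) and with the ribosomal protein score as a covariate (0.143). Over its 29 alternatives the adjusted p ran from 7.55e-09 (DESeq2) to 0.294 (additive fit), and the log2 fold change from -2.23 to -1.91.

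Genes of the pathway that iβARK acts on did not pass over both sexes. Grk2, the kinase from which the peptide derives, was at -0.06 (SE 0.07) and Grk3 at -0.12 (SE 0.10). No row named the vector, so whether reads of the vector were counted under Grk2 is not known. The Gq family genes Gnaq, Gna11 and Gna14 were at 0.07 (SE 0.10), -0.05 (SE 0.06) and -0.38 (SE 0.90). Of the phospholipase C genes, Plcb1 was at 0.08 (SE 0.11), Plcb2 at 0.35 (SE 0.22), Plcb3 at -0.34 (SE 0.12) and Plcb4 at 0.08 (SE 0.14), and the smallest adjusted p of the 9 genes was 0.527, for Plcb3. Of the 9 genes 0 passed in edgeR, DESeq2 and limma-voom and 1 had an unadjusted p under 0.05. In males Plcb3 was at -0.63 (SE 0.19) and passed when adjusted over the list alone. The list's adjusted p was 0.568, and that of the astrocyte calcium signalling list was 0.553. Another 20 lists did not pass, with adjusted p from 0.0525 for extracellular matrix genes to 0.958 for pan-reactive astrocyte genes. The test and the median pointed opposite ways, without passing, for inhibitory neuron and microglia markers and for pan-reactive astrocyte genes. The test and the mean did so for the calcium and the A2 lists.

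In males, astrocyte genes were lower and endothelial genes higher in iβARK mice. Of 25 astrocyte markers 24 were negative (median -0.38, adjusted p = 1.13e-10; adjusted p = 0.142 with an estimated correlation). Of these 11 fell when adjusted over the list alone and 0 over all genes in edgeR and limma-voom, against 3 in DESeq2 and 13 at an unadjusted p under 0.05. Glul averaged 1507 ± 194 and 1081 ± 90.0 CPM in male mCherry and iβARK mice (-0.48, SE 0.10) and Slc1a3 averaged 682 ± 146 and 442 ± 51.3 CPM (-0.63, SE 0.14), with n = 3 and 4. Astrocyte homeostasis genes (median -0.40, adjusted p = 1.73e-09; adjusted p = 0.0891 with an estimated correlation) and secreted factors (median -0.29, adjusted p = 9.18e-05; adjusted p = 0.0891 with an estimated correlation) fell too. Endothelial markers rose, with 16 of 18 positive (median 0.49, adjusted p = 3.31e-10; adjusted p = 0.0891 with an estimated correlation). Of these 9 passed when adjusted over the list alone, among them Cdh5 (0.67, SE 0.19), Vwf (1.21, SE 0.35), Tek (0.64, SE 0.19) and Cldn5, a tight junction gene of the blood-brain barrier (0.92, SE 0.27). Immediate early genes rose, with 26 of 32 positive (median 0.36, adjusted p = 8.32e-06; adjusted p = 0.476 with an estimated correlation), and 1 passed when adjusted over the list alone, 0 over all genes in edgeR, DESeq2 and limma-voom, and 9 had an unadjusted p under 0.05. Egr3, an activity-regulated transcription factor gene, was at 0.63 (SE 0.20) and Ptgs2 at 0.60 (SE 0.16). Glucocorticoid-responsive genes fell (median -0.40, adjusted p = 8.32e-06; adjusted p = 0.0891 with an estimated correlation), and 5 fell when adjusted over the list alone, among them Sgk1 (-1.13, SE 0.25) and Arrdc2 (-0.89, SE 0.21), against 0 over all genes in edgeR and limma-voom and 2 in DESeq2. Cholesterol synthesis genes (median -0.14, adjusted p = 0.0015; adjusted p = 0.0891 with an estimated correlation) and ribosomal protein genes (median -0.25, adjusted p = 2.52e-10; adjusted p = 0.605 with an estimated correlation) fell as well. The mean of the ribosomal list went from -0.24 to -0.10 without male mCherry replicate 1, to -0.15 without male iβARK replicate 3 and to -0.39 without male iβARK replicate 1. The mean of the astrocyte markers went from -0.36 to -0.23 without male mCherry replicate 1.

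Male and female mCherry mice differed in several of these lists. Astrocyte markers were higher in male than in female mCherry mice (median 0.21, adjusted p = 1.59e-05; adjusted p = 0.4 with an estimated correlation). Endothelial markers were lower (median -0.22, adjusted p = 1.7e-05; adjusted p = 0.288 with an estimated correlation), and so were immediate early genes (median -0.24, adjusted p = 0.000379; adjusted p = 0.56 with an estimated correlation). Glucocorticoid-responsive genes (median 0.24, adjusted p = 0.000133; adjusted p = 0.185 with an estimated correlation), astrocyte homeostasis genes (median 0.22, adjusted p = 3.52e-07; adjusted p = 0.183 with an estimated correlation) and ribosomal protein genes (median 0.25, adjusted p = 3.39e-09; adjusted p = 0.56 with an estimated correlation) were higher. Microglia markers were higher too (median 0.37, adjusted p = 1.7e-05; adjusted p = 0.557 with an estimated correlation). The score of glucocorticoid-responsive genes was 0.37 higher in male than in female mCherry mice, and -0.02 in male iβARK against female mCherry mice. The score of astrocyte markers was 0.22 (SE 0.11) higher in male than in female mCherry mice, and -0.13 (SE 0.10) in male iβARK against female mCherry mice.

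**Figure D2:**
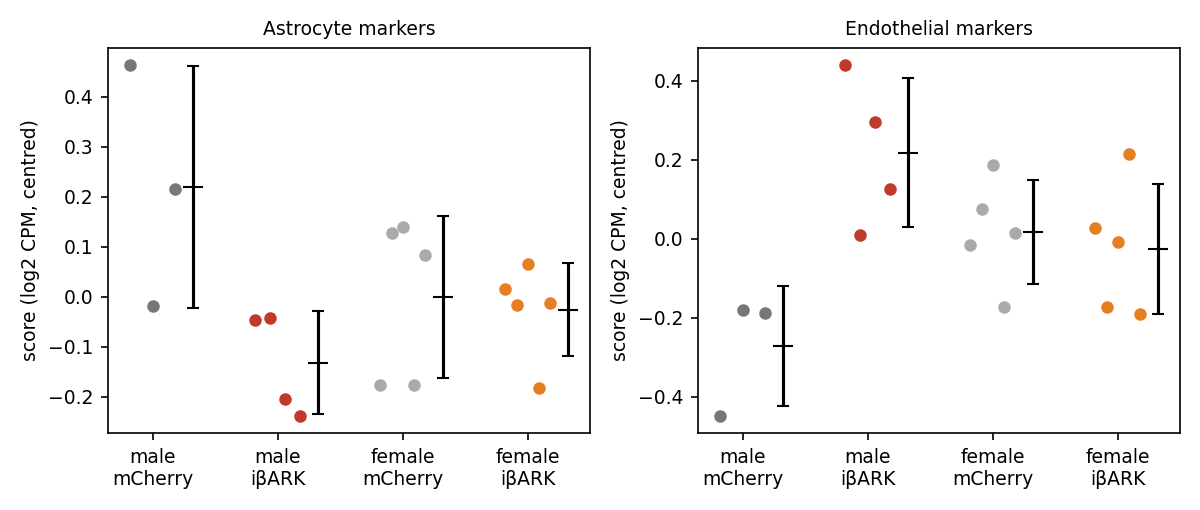
Scores of 25 astrocyte (left) and 18 endothelial markers (right), as mean log2 CPM centred over all libraries, by group, with points for libraries and bars for the mean and SD. All 4 male iβARK libraries lay below the lowest male mCherry library for astrocyte markers and above the highest for endothelial markers.

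In males interferon response genes had 30 of 30 members positive and a median of 1.60 (adjusted p = 1.67e-08; adjusted p = 0.583 with an estimated correlation). None passed when adjusted over the list alone, with 0 over all genes in edgeR, DESeq2 and limma-voom and 19 at an unadjusted p under 0.05. Their mean went from 1.59 to 0.96 without male iβARK replicate 4. The score spread widely between male iβARK libraries (SD 1.63, n = 4, exact permutation p = 0.314). Blood cell and lymphocyte markers were higher in the same comparison (median 0.47, adjusted p = 0.00777; adjusted p = 0.465 with an estimated correlation), but not among genes with a mean of at least 1 CPM (0.247) or without male iβARK replicate 1 (0.118). Their mean went from 0.91 to 2.22 without male mCherry replicate 3 and to 0.60 without male iβARK replicate 4. Their score was 0.78 higher (exact permutation p = 0.229), with 2 of the 4 iβARK libraries above every mCherry library. Antigen presentation genes (median 0.78, adjusted p = 0.00432; adjusted p = 0.718 with an estimated correlation) lost their call with the block within sex (adjusted p = 0.389). They lost it also without male mCherry replicate 2 (0.618), male iβARK replicate 1 (0.191) or male iβARK replicate 4 (0.371), and their mean went from 0.88 to 1.67 without male mCherry replicate 3. Microglia markers were lower (median -0.25, adjusted p = 0.00539; adjusted p = 0.681 with an estimated correlation), and their call was lost without male mCherry replicate 1 (0.464), male mCherry replicate 3 (0.0567), male iβARK replicate 2 (0.0512) or male iβARK replicate 3 (0.225), and with the ribosomal covariate (0.510). In fits that kept the call, their mean went from -0.23 to -0.42 without male mCherry replicate 2 and to -0.41 without male iβARK replicate 1. It shrank without male mCherry replicate 1. Excitatory neuron markers were higher (median 0.23, adjusted p = 0.0177; adjusted p = 0.476 with an estimated correlation), with the call lost without 4 libraries (highest adjusted p = 0.132, without male iβARK replicate 3), with the block within sex (0.0852) and with the ribosomal covariate (0.195). Oligodendrocyte precursor markers were lower (median -0.15, adjusted p = 0.0223; adjusted p = 0.395 with an estimated correlation), with the call lost without 3 libraries (highest adjusted p = 0.101, without male mCherry replicate 2) and with the myelin covariate (0.0946). Of the other lists that passed, myelin markers (median -0.36, adjusted p = 0.0244; adjusted p = 0.819 with an estimated correlation) lost their call without 4 libraries, with the highest adjusted p at 0.615 without male mCherry replicate 3, with the ribosomal covariate (0.101) and among genes with a mean of at least 1 CPM (0.0648). Their mean went from -0.41 to -0.74 without male mCherry replicate 1, while their score difference shrank without male mCherry replicate 3. Nuclear respiratory chain genes (median -0.08, adjusted p = 0.0191; adjusted p = 0.819 with an estimated correlation) and mitochondrially encoded genes (median -0.12, adjusted p = 0.0194; adjusted p = 0.648 with an estimated correlation) lost theirs without 3 libraries each, and with the block within sex (0.288 and 0.104). With the ribosomal covariate the mean of the respiratory genes turned from -0.09 to 0.08 (adjusted p = 0.101). Their highest adjusted p without a library was 0.261 without male iβARK replicate 4, and that of the mitochondrially encoded genes 0.691 without male mCherry replicate 1. The mean of the mitochondrially encoded genes, -0.15, turned to 0.10 without male mCherry replicate 1 and was -1.39 without male iβARK replicate 1, and their call was lost with the ribosomal covariate as well (0.0515). In all 20 lists passed in males, 7 higher and 13 lower, 0 with an estimated correlation and 6 by fry, and 12 without male iβARK replicate 3. The smallest p that an exact permutation of 3 against 4 libraries allows is 0.0286, which 5 lists reached before adjustment, among them astrocyte and endothelial markers (adjusted p = 0.234 over 41 lists).

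Gask1b was the 1 gene that passed in males, where it fell by 3.38 on the log2 scale (SE 0.45, adjusted p = 0.0109). limma-voom called 1 gene and DESeq2 64, and 1563 genes had an unadjusted p under 0.05. The call was lost with the block within sex (adjusted p = 0.155), with the male libraries fitted alone (0.0638), with the ribosomal protein score as a covariate (0.118), and without male mCherry replicate 1 (0.0573), male iβARK replicate 2 (0.103) or male iβARK replicate 3 (0.0544). Over its 28 alternatives the adjusted p ran from 7.15e-10 (DESeq2) to 0.155. At an adjusted p under 0.1 the genes named after their values were seen were Sall3 (-1.24, SE 0.20), Lrp4 (-0.86, SE 0.15) and the Wnt inhibitor Sfrp1 (-1.16, SE 0.20), which were lower, and Kcnk4 (1.42, SE 0.26) and A2ml1 (2.85, SE 0.51), which were higher.

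In females the score of interferon response genes was higher in every iβARK library than in any mCherry library. All 30 members were positive (median 1.51, adjusted p = 3.66e-25; adjusted p = 0.616 with an estimated correlation), and the score was 1.49 higher (exact two-sided permutation p = 0.00794, the smallest possible; adjusted p = 0.163 over 41 lists). Of the members 23 passed when adjusted over the list alone and 0 over all genes in edgeR and limma-voom, against 2 in DESeq2 and 25 at an unadjusted p under 0.05. Ifit1 averaged 1.47 ± 0.582 CPM in mCherry and 13.3 ± 10.9 CPM in iβARK mice (n = 5 and 5). Antigen presentation genes rose, with 18 of 18 positive (median 0.78, adjusted p = 9.4e-08; adjusted p = 0.878 with an estimated correlation), and 1 passed when adjusted over the list alone, 0 over all genes in edgeR, DESeq2 and limma-voom, and 6 had an unadjusted p under 0.05. The class II genes H2-Ab1 and Cd74 were at 1.72 (SE 0.74) and 1.84 (SE 0.79). The score of blood cell and lymphocyte markers was 0.48 higher (exact two-sided permutation p = 0.0397, adjusted p = 0.271 over 41 lists), with 2 of 5 iβARK libraries above every mCherry library, and their list did not pass camera (adjusted p = 0.0502). Microglia markers were higher (median 0.20, adjusted p = 0.000525; adjusted p = 0.878 with an estimated correlation), with the call lost without female iβARK replicate 3 (0.0519). Their mean went from 0.21 to 0.32 without female mCherry replicate 3, and their score difference shrank without female iβARK replicate 3. Complement genes were higher too (median 0.28, adjusted p = 0.0071; adjusted p = 0.878 with an estimated correlation), with the call lost without female mCherry replicate 4 (0.075). Astrocyte markers had a median of -0.04 (adjusted p = 0.663) and endothelial markers of -0.09 (adjusted p = 0.239).

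No gene passed in females in edgeR, where the smallest adjusted p was 0.963 and 723 genes had an unadjusted p under 0.05. limma-voom called 0 and DESeq2 11, 7 higher and 4 lower. The genes with the smallest p were Ifi27l2a (4.45, SE 0.98), Ifit1 (3.17, SE 0.72), Ifi207 (2.67, SE 0.63), Ifi213 (5.01, SE 1.19) and Trim25 (1.08, SE 0.26) among the positive ones. Among the negative ones they included the matricellular gene Ccn1 (-0.98, SE 0.19), Btg2 (-0.76, SE 0.18), Lrriq1 (-3.79, SE 0.92) and the muscarinic receptor gene Chrm3 (-0.71, SE 0.18). Lists that passed numbered 14, 9 higher and 5 lower. With an estimated correlation 0 passed and by fry 0, while 6 had an unadjusted exact permutation p under 0.05. Without female mCherry replicate 3, female mCherry replicate 5 or female iβARK replicate 1 there were 9, and without female iβARK replicate 3 there were 7. Among them were ribosomal protein genes (median -0.08, adjusted p = 0.0182; adjusted p = 0.94 with an estimated correlation), whose call was lost in 6 of 17 fits without a library (highest adjusted p = 0.957, without female mCherry replicate 3). Immediate early genes were lower (median -0.08, adjusted p = 0.0196; adjusted p = 0.898 with an estimated correlation), with the call lost without 4 libraries (highest adjusted p = 0.484, without female iβARK replicate 2). With the replicate number as a block the calls of myelin markers (0.0527), glutamate receptor genes (0.061) and GABA receptor genes (0.0693) were lost. With the ribosomal covariate they were lost as well (0.0765, 0.275 and 0.313).

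By camera with its preset correlation, the effect of iβARK differed between the sexes for several cell type lists. Of 100 drawn splits of the libraries, 58 gave at least 11 such lists, the real one included, so chance could not be excluded. Several of these lists also differed between male and female mCherry mice. Endothelial markers (median difference 0.51, male effect minus female effect, adjusted p = 9.27e-10; adjusted p = 0.21 with an estimated correlation) and immediate early genes (0.46, adjusted p = 1e-07; adjusted p = 0.449 with an estimated correlation) were more positive in males. Astrocyte markers (-0.27, adjusted p = 1.33e-07; adjusted p = 0.357 with an estimated correlation) and microglia markers (-0.46, adjusted p = 4.11e-06; adjusted p = 0.572 with an estimated correlation) were more negative in males. The difference for interferon response genes did not pass (median 0.05, mean -0.09, test lower, adjusted p = 0.267). The call of oligodendrocyte precursor markers (median -0.20, adjusted p = 0.00738; adjusted p = 0.354 with an estimated correlation) was lost without female iβARK replicate 3 (0.084). That of ribosomal protein genes (-0.20, adjusted p = 0.000256; adjusted p = 0.968 with an estimated correlation) was lost without 4 libraries, with the highest adjusted p at 0.383 without male mCherry replicate 1. That of microglial activation genes (-0.36, adjusted p = 0.00199; adjusted p = 0.904 with an estimated correlation) was lost without male mCherry replicate 1 (0.122), male mCherry replicate 3 (0.130) or female mCherry replicate 4 (0.0516). Without male mCherry replicate 1 the mean difference went from -0.31 to -0.19 for astrocyte markers and from -0.44 to -0.27 for microglia markers. For ribosomal protein genes it went from -0.13 to -0.28 without male iβARK replicate 1. Without male mCherry replicate 1 their male mean was -0.095, against a female mean of -0.111 with all libraries. The direction of their difference is therefore not settled. Of 42 lists 11 passed, 2 higher and 9 lower in males, with 0 at an estimated correlation, 0 by fry, and 1 at an unadjusted exact permutation p under 0.05. Without male mCherry replicate 2 there were 17. No gene passed in edgeR (smallest adjusted p = 0.805, 1036 at an unadjusted p under 0.05), limma-voom called 0 and DESeq2 7. The genes with the smallest p were A2ml1 (3.10, SE 0.62), Iffo1 (0.64, SE 0.15), Cgnl1 (0.99, SE 0.24), Sox13 (1.19, SE 0.29) and Prickle3 (1.98, SE 0.51) among those more positive in males. Lrp4 (-0.94, SE 0.19), Fgf1 (-0.80, SE 0.17), Trp53bp2 (-0.78, SE 0.17), Sall3 (-1.20, SE 0.26) and Gask1b (-2.52, SE 0.57) were the first of those more negative in males. Across the 19839 features, which are not independent replicates, male and female effects had a Pearson r of 0.129 and a Spearman rho of 0.0694, and 52.1% had the same sign.

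**Figure D3:**
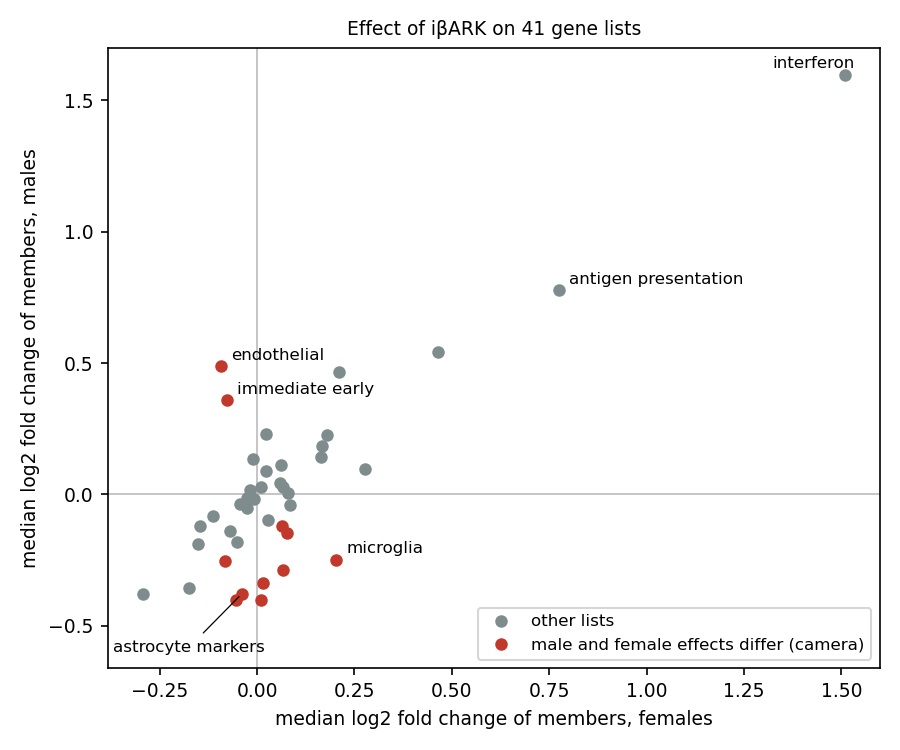
Median log2 fold change of the members of 41 gene lists in females (x axis) and males (y axis); each point is a list, in red where camera found the effects to differ. The interferon list lies at 1.51 in females and 1.60 in males, and the endothelial list at -0.09 and 0.49.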

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

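The tests of microglia, of the male controls, of the scaling, of the correlation with blood markers and of the lists without mt-Nd4 were chosen only after the results were seen, and so was the use of the planned fits without a library and with the replicate block as tests of an explanation. The genes scanned for libraries that stand apart were listed after values had been seen.

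The tables argue against more microglia as the source of the higher interferon response genes in iβARK mice, since the interferon score differed by 1.33 (SE 0.39) more than the microglia score, which differed by -0.01 (SE 0.16), and by 1.39 (SE 0.61) more in males and 1.26 (SE 0.50) more in females, where the microglia score differed by -0.24 (SE 0.24) and 0.23 (SE 0.20), though the microglia list passed in females (adjusted p = 0.000525; adjusted p = 0.878 with an estimated correlation). In females they argue against a single library too, since all 5 iβARK libraries scored above every mCherry library. In males 2 of 4 did, and the list's mean went from 1.59 to 0.96 without male iβARK replicate 4. Reliance on few libraries stays open there. The interferon list passed in 17 of the 17 fits that left one out (camera with its preset correlation, adjusted p = 0.245 with an estimated correlation and all libraries). That decides little, since every split of the libraries that was counted also gave called lists. More lymphocytes stays open: with the blood cell and lymphocyte score as a covariate the difference fell from 1.32 (SE 0.49) to 0.32 (SE 0.34), and over 17 libraries the scores correlated (Pearson r = 0.869, permutation p = 1e-05, the smallest possible, adjusted p = 3e-05; Spearman rho = 0.843, p = 6e-05, adjusted p = 0.00018; 3 relations). The 5 blood and lymphocyte markers above 1.5 (Cd3g, Cd8a, Cd79a, Cd3e and Nkg7) had means of at most 0.521 CPM, while Trbc2 was at 0.19 (SE 0.13) with 8.03 CPM, the 4 hemoglobin genes lay between -0.08 and 0.14, and the list did not pass among genes with a mean of at least 1 CPM (adjusted p = 0.156). Without male iβARK replicates 1 and 4 the correlations were r = 0.760 (permutation p = 0.001, adjusted p = 0.001) and rho = 0.775 (p = 0.00105, adjusted p = 0.00105). With group means subtracted they were r = 0.833 (permutation p = 5e-05, adjusted p = 7.5e-05) and rho = 0.801 (p = 2e-04, adjusted p = 3e-04). Lymphocytes may therefore accompany the response or carry it. A response to iβARK itself stays open as a hypothesis, untested against these. The iβARK and mCherry mice got different vectors, and no group went without one. A response to iβARK cannot be told apart here from one to another difference between the vectors.

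Astrocyte genes were lower in iβARK males. The replicate block decides nothing about a batch, since the numbers 1 to 3 occur in both male groups (adjusted p = 5.34e-08 with the block; adjusted p = 0.142 without it and with an estimated correlation). Male mCherry libraries that stand apart stay open: their score lay 0.22 (SE 0.11) above that of female mCherry mice, and male iβARK mice lay 0.35 (SE 0.11) below them and 0.13 (SE 0.10) below female mCherry mice. A lower share of astrocytes stays open as well, since 3 of 25 members lay over 2 SE from the list's median against 1.14 by chance (binomial p = 0.103). An effect of iβARK on astrocyte genes in males, and a difference between the sexes in it, stay open as hypotheses.

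Ribosomal protein genes were lower in iβARK mice. Other size factors decide nothing about the scaling, since they moved the median of all genes by under 0.01 and camera compares members with other genes (larger adjusted p = 1.18e-10). Removing each library's trend with transcript length did not reduce the score difference, which was -0.18 (SE 0.13) before and -0.19 (SE 0.11) after. The slope of the trend differed by -0.004 (SE 0.023) over both sexes. These values argue against the measured trend as the source of the score difference. Both score differences lay within 2 SE of 0, short of the bar set beforehand. The scores alone therefore do not settle that there is a difference to explain. Members had a median exonic length of 1806 bases against 3977 for other genes. No biological explanation was tested.

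Other splits of the same libraries were counted for each set of calls. For the sexes of mCherry mice 1 of 56 splits gave 8 genes or more, the real one, and the highest other gave 6. Most of the called features are sex-linked genes, which part correctly labelled mice in any case. This therefore checks the labels and decides nothing about other differences between the sexes, whose lists were not counted in splits. Chance could not be excluded for genes over both sexes (12 of 100 drawn splits, real value 1, highest other 378), or in males (7 of 35, 1 and 34). For genes in females and for the interaction the real value was 0, so all 100 splits gave as many and this decides nothing (highest others 5 and 114). Nor could it for lists over both sexes (15 of 100, 20 and 28), in males (10 of 35, 20 and 29), in females (12 of 100, 14 and 19) or for the interaction (58 of 100, 11 and 29). The split with 378 genes set male mCherry 1 and 2, male iβARK 1 and 2, female mCherry 1, 2 and 3 and female iβARK 1 and 5 apart. It and the splits with 114 and 34 genes point to a structure of the samples other than the treatment. Of the same kinds of split, 88 of 100, 93 of 100 and 28 of 35 gave no gene. The replicate number tracked this structure in part. In the splits with 378 and 114 genes, male replicates 1 and 2 were parted from 3 and 4. With 114 genes, female replicates 1 and 2 were parted from the others, except female iβARK 4. The females of the split with 378 did not follow this line, and the male split along it gave 0 genes. In each group but male mCherry, replicates 1 and 2 also had the largest shares of counts in rows named by other identifiers. The source was not tested. The splits with 378, 114 and 34 genes parted 3 of 8, 1 of 8 and 1 of 3 pairs of libraries with one replicate number, where the real split parts all. The 3 male splits that part no such pair gave 0, 0 and 1 genes, and the 1 that gave as many as the real split set male mCherry 2 and 3 and male iβARK 2 and 3 apart. With that number as a block there was 1 gene in males. Of the 8 male splits that part as many replicate numbers as the real one, 2 gave as many genes (highest other 1) and 4 as many lists (highest other 23). In females 2 of 14 such splits gave as many lists (highest other 14). Over both sexes, 1 of 2 such drawn splits, the real one, gave as many genes and as many lists (highest others 0 and 14).

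Single libraries stood apart from their group in 14 of 358 scanned groups of genes and scores, where chance gives 17.9. The male mCherry group (n = 3) was not scanned, so this says nothing about its libraries. The gap to the nearest library, as a share of the group's range, was 0.760 for Grk2 in female mCherry 3, 0.936 for Plpp3 in male iβARK 4, 0.776 for Ly6a in female iβARK 4 and 0.760 for Nrgn in female iβARK 3. It was 0.848 for Gpr17 in male iβARK 1, 0.913 for Sall3 in male iβARK 3, 0.799 for Sfrp1 in female iβARK 4, 0.933 for Ccn1 in male iβARK 2 and 0.880 for Fos in female iβARK 2. Among scores it was 0.822 for upper layer markers in female iβARK 1, 0.891 for glucocorticoid-responsive genes in male iβARK 2, 0.732 for oligodendrocyte precursor markers and 0.754 for extracellular matrix genes in female iβARK 3, and 0.792 for mitochondrially encoded genes in female iβARK 5. The last came from mt-Nd4, at 182 CPM in that library and 0 in the other 4 of its group; without that gene the largest gap was 0.351.

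The male effect minus the female effect passed camera for 11 lists, none with an estimated correlation. Their medians were -0.27 for astrocyte markers, -0.46 for microglia markers, -0.20 for oligodendrocyte precursor markers, 0.51 for endothelial markers, -0.43 for astrocyte homeostasis genes and -0.21 for secreted factors. They were -0.36 for microglial activation genes, 0.46 for immediate early genes, -0.18 for mitochondrially encoded genes, -0.20 for ribosomal protein genes and -0.35 for glucocorticoid-responsive genes. The mitochondrially encoded list passed with mt-Nd4 (adjusted p = 0.0331) and without it (adjusted p = 0.0224). It lost its call in 9 of the 17 fits that left out a library (highest adjusted p = 0.615, without male mCherry replicate 1), with the block within sex (0.177) and with the ribosomal covariate (0.0555). Its mean of -0.02 ran from -1.26 without male iβARK replicate 1 to 1.09 without female iβARK replicate 5, so its sign is not settled. The call of microglial activation genes was lost without 3 libraries (highest adjusted p = 0.130, without male mCherry replicate 3).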

How the results depend on the processing

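The covariate fits, the exact permutation of list scores, the other size factors and the block within sex for lists, and the lists without mt-Nd4 were chosen only after seeing the data. Of 7939 alternatives for 283 values of named genes 7877 kept their side of the threshold (6 of them, not passing, changed sign), 21 lost and 41 gained a call, and 0 reversed. Most of these values did not pass as reported, so that they kept their side shows little. Gask1b kept its call in 22 of 29 alternatives over both sexes and in 22 of 28 in males. Of 1748 alternatives for 65 called lists 1422 kept the direction of the test and the call, 326 lost the call and 0 passed in the opposite direction. With other size factors the median of all genes was at most 0.00858 on the log2 scale, and no count changed. Calls over both sexes, in males, in females, for the interaction and between the sexes of mCherry mice were 1, 1, 0, 0 and 8. DESeq2 gave 55, 64, 11, 7 and 44. Without a filter they were 12, 11, 1, 0 and 21. At an adjusted p under 0.1 males had 6 and the sexes 13. The replicate block within sex gave 0 over both sexes and 1 for the interaction, and in males its 1 call was Gm21974, not Gask1b. The replicate block over all libraries gave 1, 1, 0, 0 and 6, and 17, 21, 11 and 12 lists; it ended no other call of an iβARK effect than those of the lists given above, and between the sexes it ended those of Eif2s3x (adjusted p = 0.0727) and MSTRG.35445 (0.195). The additive fit and the fit with no sex term gave 0, male libraries alone 0 and female libraries alone 1. The myelin covariate gave 2 over both sexes and 15 between the sexes, and the ribosomal covariate 0 over both sexes and 0 in males, where it left 11 lists. Leaving out a library gave 0 to 2 genes over both sexes, 0 to 4 in males, 0 to 0 in females, 0 to 1 for the interaction and 8 to 13 between the sexes. It gave 16 to 22 lists over both sexes, 12 to 20 in males, 7 to 15 in females and 9 to 17 for the interaction. List counts of 20, 20, 14 and 11 became 0, 0, 0 and 0 with an estimated correlation, 1, 6, 0 and 0 by fry, and 1, 0, 0 and 0 by exact permutation. The correlation of the male and female effects, 0.129, was 0.103 above 1 CPM, 0.101 with the replicate block and 0.0641 to 0.146 without a library. The cause was not tested, beyond fewer libraries or other numbers of genes tested.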
